A study of Mus musculus with 12 samples.

How the data were processed

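Gene expression was measured in mouse retina on 12 two-colour Agilent whole-genome arrays. Per the labels, the right eyes of male C57BL/6 mice aged 5 weeks received an intravitreal injection of phosphate-buffered saline (PBS) or of gold or silicate nanoparticles of 20 or 100 nm, and retinas were taken 7 days later. There were 12 mice per group and 4 retinas were pooled per tube, which gives 3 tubes per group. The sample annotation writes the particle sizes with the unit nM, and the growth protocol gives them as diameters in nm, which is the reading used here. Each array held RNA from a particle tube in Cy5 and RNA from PBS-injected eyes in Cy3, and the dyes were not exchanged on any array. A dye effect of a probe is therefore part of every ratio of particle to PBS and cancels between particle groups.

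The deposited files for each array hold scanner output in units of intensity, extracted with Agilent Feature Extraction 11.0.1.1 per the file headers, while the submitters' processing notes name version 9.3.2.1. The deposited columns of intensity used here were the median foreground signal, the median local background and, as an alternative, the processed signal that Feature Extraction had background-subtracted and dye-normalized. The log10 ratio of Cy5 to Cy3 in the same deposited files served to find the scale of the series' value table. The deposited value table holds log2 ratios of Cy5 over Cy3, a scale and direction that were found by setting each column against the log10 ratio of its array. The slope was between 3.3 and 3.32 and the correlation across spots, which are not independent replicates, between 0.942 and 0.995. Column medians of that table were 0.016, 0.033 and 0.045 for gold 20 nm, 0.056, 0.048 and 0.045 for gold 100 nm, 0.087, 0.048 and 0.091 for silicate 20 nm, and 0.074, 0.048 and 0.11 for silicate 100 nm. How the authors centred those columns stays unknown.

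Background was corrected with the normexp method of limma with an offset of 50, and each array was normalized by loess, with the 1377 control spots at weight 0. Spots marked as outliers by Feature Extraction, 149 to 257 per array, were left out, and no spot was saturated. Spots of one probe were averaged, which left 39429 probes from 43020 spots. Probes were named by their RefSeq accession without its version through a RefSeq gene table of GRCm38.p6, used for names only because the arrays were annotated on mm9 per the file headers. Of 32334 RefSeq-type accessions, 6279 had no match, and 26055 probes received a symbol. Other probes kept the name in the deposited files. A probe was kept when it was well above background in at least 1 channel on all 3 arrays of at least 1 group, which held for 28460 probes. The probe with the highest mean log2 intensity stood for its gene. This gave 23237 genes, of which 15592 had a symbol, 4389 had more than 1 kept probe and 38 lacked the value of an array.

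Log2 ratios were tested with limma's lmFit and eBayes (limma 3.58.1 in R 4.3.3, with data.table version 1.17.8), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A single fit over all 12 arrays with 4 group means gave 12 contrasts. These were each particle group against PBS, the mean of the 4 groups against PBS, gold against silicate, 100 nm against 20 nm, the difference of the size effects of the materials, and the 4 differences between single groups. Every adjusted p below is from limma unless a permutation test is named. For a gene not well above background in one channel on all arrays of a group, the fold is a lower bound, taken against the higher of the probe's own level and the lowest level of any probe well above background in that channel. These bounds rest on normalized single channels and stay open to dye bias. PBS was in Cy3 on all arrays, so its level was read from that channel.

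Replicate numbers equal slide numbers. Each of the 3 slides carried 1 array of each group, always at the same place on the slide, so place and group cannot be told apart. Deviations from the group means correlated between arrays of slide 1 at 0.889 to 0.934, of slide 2 at 0.0816 to 0.831 and of slide 3 at 0.555 to 0.919, correlations across genes. The file headers show the shared slide, so the replicate number pairs the arrays. The main fit and the main list tests hold no slide term and do not use this pairing. The replicate block and the random block use it. Which PBS tube lies on which array is not stated. The median SD of a gene's Cy3 level was 0.0544, 0.0488 and 0.0872 within slides 1, 2 and 3 and 0.164 between slides. In Cy5 it was 0.116, 0.101 and 0.197 within the slides. The 4 arrays of a slide were therefore taken to share 1 PBS tube. Some genes, chosen after their values were seen, varied more in Cy3 over the 4 arrays of slide 3. The SD was 2.44 for Lcn2, 1.74 for Lyz2 and 0.71 for Cd74, but 0.03 for Ms4a7 and 0.05 for Cx3cr1. The shared tube is thus an assumption, and Cy3 levels of such genes on slide 3 are uncertain. Where nothing else is said, n counts arrays, and the p-values measure the spread between arrays. In comparisons with PBS, the fit without a block counts the 4 uses of a PBS tube as independent. For the 4 groups together, its p-values therefore understate the spread between PBS tubes. For a single group, the 3 arrays lie on 3 slides, so that spread enters the residual. The pooled residual still counts arrays that share a tube as independent.

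In all, 30 gene lists were written from textbook knowledge, with 471 distinct genes, of which 448 were tested and 5 had no matched probe. Lists with at least 5 tested genes entered limma's camera with a preset inter-gene correlation of 0.01, camera with an estimated correlation, and fry, with adjustment over the 30 lists of a contrast. Calls were also made with adjustment over the list alone. The genes named in the text followed a rule. In each particle group the 6 largest rises and falls past the threshold with one sign on all 3 arrays were named, and for the 4 groups together the 8 largest each way with one sign on at least 10 arrays. Between particle groups, the 4 largest each way were to be named, or the 2 smallest p each way where none passed. From each list up to 4 members with the smallest p were taken. The always-named genes, 9 in number, included Gfap, Vegfa, Kdr, Flt1, Hmox1, Mt1, Mt2 and Hspa1b, and Hspa1b had no matched probe. Results of some genes that the rule names are not reported here. Genes outside the rule are marked in the text as chosen after their values were seen. Groups, tests, lists, the naming rule and most alternatives were fixed before the data were examined.

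Alternatives were the processed signals, array median centring, Aquantile, no filter and a stricter filter, the mean of all probes, the replicate block, the slide as a random block by duplicateCorrelation (correlation 0.49), an intensity trend with robust spread, only the groups of a comparison, the deposited value table, and each array left out in turn. Leaving out each slide, leaving out both silicate arrays of slide 3, and a fit of separate channels with 3 PBS tubes were added after seeing the data.

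The fits were tested on simulated data with 23199 genes, of which 67, 67 and 66 were shifted by 0.5, 1 and 2 log2. For silicate 20 nm against PBS, the fit without a block recovered 50.7%, 70.1% and 92.4% of the shifts with 46 false calls. The random block recovered 52.2%, 74.6% and 92.4% with 50 false calls, and the fixed block 77.6%, 83.6% and 98.5% with 911 false calls. For the 4 groups together, no block gave 82.1%, 92.5% and 100% with 1268 false calls, the random block 62.7%, 86.6% and 98.5% with 183, and the fixed block 91%, 98.5% and 100% with 5120. The fixed block leaves out the spread of the PBS tubes, and the fit without a block treats the 4 uses of a PBS tube as independent. Genes that also pass with the random block are therefore given first in comparisons with PBS. With 183 and 50 false calls beside 67, 67 and 66 planted shifts, the random block did not hold errors to the threshold either. A pass with it therefore does not establish a change. For gold against silicate, no block recovered 52.2%, 77.6% and 87.9% with 3 false calls, the random block 59.7%, 92.5% and 93.9% with 10, and the fixed block 62.7%, 92.5% and 97% with 11. In the same comparison, a gene list shifted by 0.5 log2 was found at an adjusted p of 5.28e-05, and of 0.0263 with an estimated correlation, with 0 other lists called. The genes were simulated independently of each other. This check therefore cannot show how often lists whose genes move together are called wrongly. On 44397 simulated spots, a planted log2 ratio of 1 was recovered as 1 for bright and 1.05 for dim spots.

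Well above background were 69.5% to 74.8% of spots in Cy3 and 68.3% to 73.8% in Cy5. Median signals were 199 to 262 in Cy3 and 227 to 297 in Cy5, over median backgrounds of 34.5 to 42 and 56 to 59. The number of arrays limits the precision. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.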

Results

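The series measured how intravitreal gold or silicate nanoparticles change gene expression in the mouse retina 7 days after injection. There were 4 particle groups, gold and silicate at 20 and 100 nm, each with 3 arrays, and every array set a pool of 4 particle-injected retinas against a pool of 4 PBS-injected retinas. Values are log2 ratios of particle over PBS, positive where the particle tube was higher. PBS retinas served as the background on each array, and their levels are given as normalized log2 intensity.

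The arrays differed by slide, and on slide 3 also by material. Macrophage and microglia markers, such as the protease Ctss and the complement gene C1qa, had median log2 ratios of -2.50, -3.11, -1.84 and -2.43 on the arrays of slide 1 for gold 20 nm, gold 100 nm, silicate 20 nm and silicate 100 nm. On slide 2 the medians were 1.01, 0.37, 0.37 and 0.24, and on slide 3 they were -0.43, -0.71, 3.3 and 3.54. The level of Ms4a7, a membrane protein of macrophages chosen after its values were seen, was 13.33 in the PBS tube of slide 1, and 7.12 and 8.03 in the PBS tubes of slides 2 and 3. It reached 14.49 and 15.07 in the silicate 20 nm and 100 nm tubes of slide 3. S100a8, a calcium-binding protein of neutrophils chosen in the same way, was at 15.69 in the PBS tube of slide 1, and at 6.48 and 6.71 in the others. In the particle tubes it was at 7.51 to 8.80 on slide 1, at 11.16 and 10.06 in the silicate tubes of slide 2, at 12.37 and 14.56 in those of slide 3, and at 6.38 to 6.55 in the gold tubes of slides 2 and 3. Log2 ratios correlated across genes, which are not independent replicates, at 0.853 to 0.947 between arrays of slide 1 and at 0.459 to 0.645 between those of slide 2. On slide 3 the correlation was 0.923 between the silicate arrays, with a median of 0.0381 over all 6 pairs (lowest -0.00687), and arrays of one group had -0.633 to 0.298. Between slide 1 and those silicate arrays, the correlation was -0.721 to -0.535. The dyes are stated for every array and the PBS tubes differed between slides, so the direction of the ratios was kept.

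**Figure D1:**
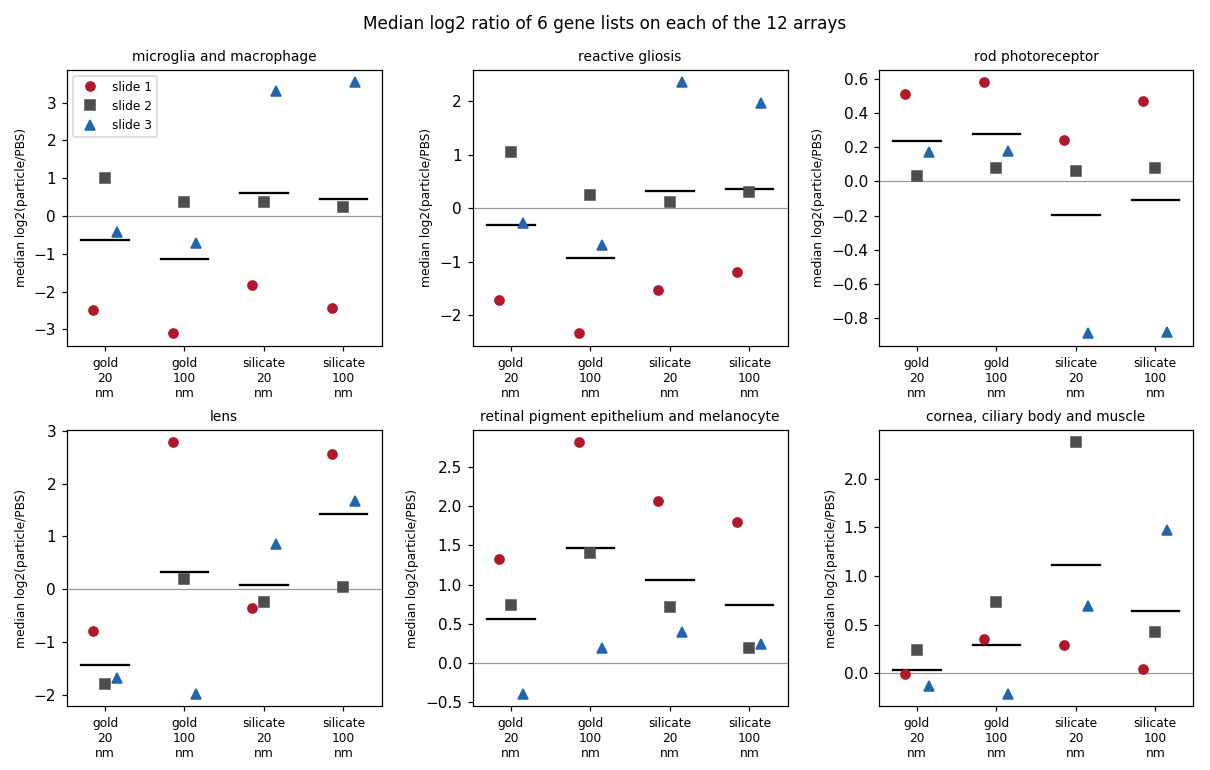
Median log2 ratio of particle over PBS for 6 gene lists on each of the 12 arrays, by particle group on the horizontal axis, with a marker for each slide and a bar for the mean of 3 arrays. Macrophage and microglia markers stand at -3.11 to -1.84 on slide 1 and at 3.3 and 3.54 on the silicate arrays of slide 3.

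With gold particles of 20 nm, Serpina6, the corticosteroid-binding globulin, was higher, with a log2 ratio of 2.74 ± 0.17 (SD, n = 3, adjusted p = 2.97e-06), at least 6.62-fold, since its probe was not well above background in PBS. Prokr1, a prokineticin receptor, rose by 1.98 ± 0.50 (adjusted p = 0.00427), and was well above background in 1 of the 3 PBS channels. The spindle protein gene Dlgap5 rose by 1.79 ± 0.26, at least 3.46-fold (adjusted p = 0.000192), and the RNA export factor gene Nxf3 by 1.72 ± 0.19, at least 3.28-fold (adjusted p = 0.000249). Tmigd1 and Sntn rose by at least 3.18-fold and at least 2.86-fold (adjusted p of 0.00461 and 0.00297). A further probe of Dlgap5 read 0.54. These 6 genes were called higher in all 4 particle groups, and the particle side was in Cy5 on every array. Among the genes that fell, Eps8l1, a regulator of actin, had a log2 ratio of -1 ± 0.52 (adjusted p = 0.045). All of these genes passed also with the slide as a random block.

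Cryge, which encodes a gamma-crystallin of lens fibres, showed the largest fall with gold 20 nm, with a log2 ratio of -3.32 ± 0.53 (SD, n = 3, adjusted p = 0.0498), and its adjusted p was 0.0757 with the random block. Lrrc30, the dynein gene Dnaic2, Gfod2 and Zmynd19 fell with log2 ratios of -0.51, -0.43, -0.43 and -0.28, with adjusted p of 0.0571 to 0.0712 with the random block. In all, 149 genes rose and 15 fell of 23237. With the random block 119 rose and 6 fell, and 110 of the 125 were also called without it. The replicate block called 648 higher and 390 lower, a fit that leaves out the spread of the PBS tubes. None of the 30 lists held a member that passed over all genes tested, and lens had 4 lower members when adjusted over the list alone. Without slide 1, 54 genes passed, without slide 2 it was 12, and without slide 3 it was 8.

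By camera, lens genes were lower as a group with gold 20 nm, with a median log2 ratio of -1.49 over 17 genes (adjusted p = 1.72e-07), and blood genes with a median of -0.90 over 7 genes (adjusted p = 0.0121). Markers of retinal pigment epithelium and melanocytes, all 13 of them above 0, had a median of 0.50, rods one of 0.23 over 22 genes and retinal ganglion cells one of 0.19 over 14 genes (adjusted p = 0.0121 for each). With an estimated correlation, the adjusted p was 0.627 for blood and 0.862 for the other 4 lists, so no call held. Lens medians were -0.79, -1.80 and -1.69 on slides 1, 2 and 3. Those of the pigment epithelium list were 1.32, 0.74 and -0.39, those of rods 0.51, 0.03 and 0.17, those of blood -0.06, -0.22 and -1.49, and those of ganglion cells 0.67, 0 and 0.03. Without slide 1, the medians of pigment epithelium, rods and ganglion cells were 0.23, 0.11 and -0.04, with adjusted p of 0.126, 0.548 and 0.732. The macrophage and microglia medians of these 3 arrays were -2.50, 1.01 and -0.43. With processed signals the rod list did not pass (adjusted p = 0.277).

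With gold particles of 100 nm, Serpina6 was higher, as in the other groups, with a log2 ratio of 2.57 ± 0.15 (SD, n = 3, adjusted p = 5.12e-06), at least 5.94-fold. Dusp8, a phosphatase of MAP kinases, fell with a log2 ratio of -0.57 ± 0.07 (adjusted p = 0.0032), and the X-linked gene Xlr3b with one of -1.49 ± 0.62 (adjusted p = 0.00898). A further probe of Xlr3b read -1.08. Dnaic2 fell with a log2 ratio of -0.44 ± 0.12 (adjusted p = 0.022). These 4 genes passed with the random block as well.

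The 5 other large rises with gold 100 nm, those of Optc, Penk, Slc26a4, Gpx3 and Slc13a4, did not pass with the random block. Optc, a proteoglycan of the vitreous, rose 12.8-fold with a log2 ratio of 3.68 ± 0.16 (SD, n = 3, adjusted p = 0.022, and 0.097 with the random block). Its level was 7.47 to 7.99 in the PBS tubes. Penk, the enkephalin precursor, rose 9.26-fold (adjusted p = 0.0339, and 0.0864 with the random block), the anion exchanger gene Slc26a4 7.36-fold (0.0433 and 0.109), the secreted glutathione peroxidase gene Gpx3 6.21-fold (0.0464 and 0.144) and the sulfate transporter gene Slc13a4 5.18-fold (0.044 and 0.143). Xlr4a, Anp32a and Lrrc30 fell with log2 ratios of -1.17, -0.90 and -0.44, and with adjusted p of 0.118, 0.0893 and 0.116 with the random block. A further probe of Anp32a read -0.11. The glycolytic enzyme gene Eno1 rose with a log2 ratio of 0.44 and the erythrocyte anion exchanger gene Slc4a1 fell with one of -0.35 (adjusted p of 0.0468 and 0.0491, and 0.109 and 0.125 with the random block).

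In total 193 genes rose and 35 fell with gold 100 nm. With the random block 138 rose and 19 fell, 149 of them shared with the first count, and with the replicate block 890 rose and 674 fell. Without slides 1, 2 and 3 in turn, 34, 4 and 28 genes passed. Pigment epithelium genes were higher as a group by camera, with a median log2 ratio of 1.55 (adjusted p = 8.02e-07, and 0.746 with an estimated correlation). Their medians were 2.81, 1.40 and 0.19 on the 3 slides, and the call held without slide 1 at a median of 0.93. Interferon response, with a median of -1.02 over 20 genes, and reactive gliosis, with one of -0.90 over 18 genes, were lower as groups (adjusted p of 0.011 and 0.0109, and 0.848 for both with an estimated correlation). On the 3 slides, the interferon medians were -2.69, 0.31 and -0.68 and the gliosis medians -2.34, 0.24 and -0.69, next to macrophage and microglia medians of -3.11, 0.37 and -0.71. Without slide 1 neither passed (adjusted p of 0.782 and 0.581). Rod genes had a median of 0.23 (adjusted p = 0.011, and 0.848 with an estimated correlation) and blood genes one of -0.75 with Slc4a1 lower (0.0209 and 0.519). Without slide 1 the rod list had an adjusted p of 0.581, and with processed signals one of 0.196. The lens list did not pass at a median of 0.46, and 4 of its members were lower when adjusted over the list alone.

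With silicate particles of 20 nm, Hdc, the enzyme gene of histamine synthesis, fell with a log2 ratio of -1.26 ± 0.42 (SD, n = 3, adjusted p = 0.00548), and Csrp3, a muscle LIM protein gene, fell with one of -1.32 ± 0.26 (adjusted p = 0.00563). The spindle checkpoint kinase gene Bub1b fell with a log2 ratio of -1.06 ± 0.27 (adjusted p = 0.0104), the aryl hydrocarbon receptor repressor gene Ahrr with one of -0.87 ± 0.13 (adjusted p = 0.00563), and Nek11 with one of -0.66 ± 0.26 (adjusted p = 0.0412). A further probe of Ahrr read -0.18. Serpina6 rose by a log2 ratio of 2.51 ± 0.06 (adjusted p = 4.54e-06), at least 5.71-fold. Vegfa, the main growth factor of blood vessels, rose 1.32-fold, with a log2 ratio of 0.41 ± 0.13 (adjusted p = 0.0281), and Ankrd37, a gene induced by hypoxia, fell with one of -0.47 ± 0.05 (adjusted p = 0.0285). A further, dimmer probe of Vegfa read -0.04. All of these passed with the random block.

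Fbln1 of the extracellular matrix, Optc, the keratin gene Krt19, Gpx3 and Slc13a4 rose 8.44-fold, 8.16-fold, 7.92-fold, 7.29-fold and 5.94-fold with silicate 20 nm (adjusted p of 0.0247 to 0.0438), and missed the threshold with the random block at adjusted p of 0.0642 to 0.136. Anp32a fell with a log2 ratio of -0.80, the clock gene Per2 rose with one of 0.26 and the basal keratin gene Krt14 with one of 1.81 ± 1.38 (adjusted p of 0.0978, 0.0917 and 0.12 with the random block). There were 370 genes higher and 115 lower. With the random block 248 were higher and 41 lower, 276 of them shared with the first count, and with the replicate block 1220 were higher and 817 lower. Without slides 1, 2 and 3 in turn, 49, 8 and 176 genes passed, and without both silicate arrays of slide 3 it was 222. Processed signals called 50.7% of the changed genes higher, loess 76.3% and median centring 87.7%.

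Corneal, ciliary body and muscle genes were higher as a group with silicate 20 nm, with a median log2 ratio of 1.31 over 16 genes and with Krt14 the only member past the threshold (adjusted p = 0.00941, and 1 with an estimated correlation). Their medians were 0.29, 2.37 and 0.69 on the 3 slides. Pigment epithelium genes had a median of 0.88 (adjusted p = 0.000768, and 1 with an estimated correlation), with slide medians of 2.06, 0.71 and 0.39. Muller glia genes had a median of 0.35 over 14 genes, with 2 members higher when adjusted over the list alone (adjusted p = 0.032, and 0.438 with an estimated correlation), and fry's adjusted p for them was 0.0417. Their slide medians were 0.41, 0.13 and 0.58. These 3 calls held without slide 1. Macrophage and microglia medians were -1.84, 0.37 and 3.3 on the same arrays.

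With silicate particles of 100 nm, Prokr1 rose with a log2 ratio of 1.83 ± 0.48 (SD, n = 3, adjusted p = 0.00765), and was well above background in 1 of 3 PBS channels. Sntn and Dlgap5 both rose at least 3.28-fold (adjusted p of 0.00154 and 0.000265) and Rag1, a recombinase of lymphocyte receptor genes, at least 2.78-fold (adjusted p = 0.00293). The desmosomal cadherin gene Dsc3 rose at least 2.85-fold (adjusted p = 0.0226) and Tmigd1 at least 2.73-fold (adjusted p = 0.00994). These 6 genes, too, were called higher in all 4 groups, and a further probe of Dlgap5 read 0.23. The microtubule adaptor gene Hook3 fell with a log2 ratio of -0.46 ± 0.19 (adjusted p = 0.0269) and the lysosomal sulfatase gene Arsg with one of -0.43 ± 0.15 (adjusted p = 0.0214). These 8 genes passed with the random block as well. Ahrr, Lrrc30, Hspb6 and Ect2 fell with log2 ratios of -0.59, -0.50, -0.50 and -0.39, and the chaperone gene Hspa8 rose with one of 0.30, all 5 with adjusted p of 0.0645 to 0.133 with the random block. Further probes read 0.03 and -0.10 for Hspa8.

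With silicate 100 nm, 199 genes rose and 31 fell. With the random block 175 rose and 17 fell, 172 of them shared with the first count, and with the replicate block 663 rose and 275 fell. Without slides 1, 2 and 3 in turn, 41, 7 and 37 genes passed, and without both silicate arrays of slide 3 it was 129. The share of higher genes was 86.5%, and 63.5% with processed signals. Lens genes were higher as a group, all 17 of them above 0, with a median log2 ratio of 1.25 (adjusted p = 0.000133, and 0.985 with an estimated correlation). Their medians were 2.56, 0.04 and 1.68 on the 3 slides, and the call held without slide 1. Pigment epithelium genes had a median of 0.52 (adjusted p = 0.0212, and 0.985 with an estimated correlation), with slide medians of 1.80, 0.19 and 0.24 and an adjusted p of 0.447 without slide 1. Macrophage and microglia medians were -2.43, 0.24 and 3.54.

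Across the 4 particle groups together, Vegfa was higher on 12 of 12 arrays, 1.25-fold, with a log2 ratio of 0.32 ± 0.12 (SD, n = 12, adjusted p = 0.000573, and 0.0282 with the random block). Its level was 12.10 to 12.12 in the PBS tubes, and a dimmer probe of the gene read -0.06. Xlr3b was lower on 12 of 12 arrays, with a log2 ratio of -0.94 ± 0.47 (adjusted p of 0.000302 and 0.0197), and a further probe read -0.74. Eps8l1 fell with a log2 ratio of -0.69 ± 0.42 (0.00125 and 0.0449). The ribosomal protein gene Rps14 rose by 0.38 ± 0.14 (0.000602 and 0.0306) and the respiratory chain gene Uqcrh by 0.29 ± 0.12 (0.00137 and 0.0408), with 0.26 at a further probe. Hspa8 rose by 0.28 ± 0.07 (0.000278 and 0.0397) at a probe with a level of 16.99. Its further probes, at levels of 12.46 and 15.63, read -0.10 and -0.13. The further probes of Vegfa and Hspa8 did not rise, so a dye effect of the called probe stays open for both genes. Serpina6 rose with a log2 ratio of 2.54 ± 0.18 (n = 11, adjusted p = 7.68e-09), and was not well above background in PBS. Its PBS level was 6.12 to 6.23 and its particle level 8.56 to 9.00.

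**Figure D2:**
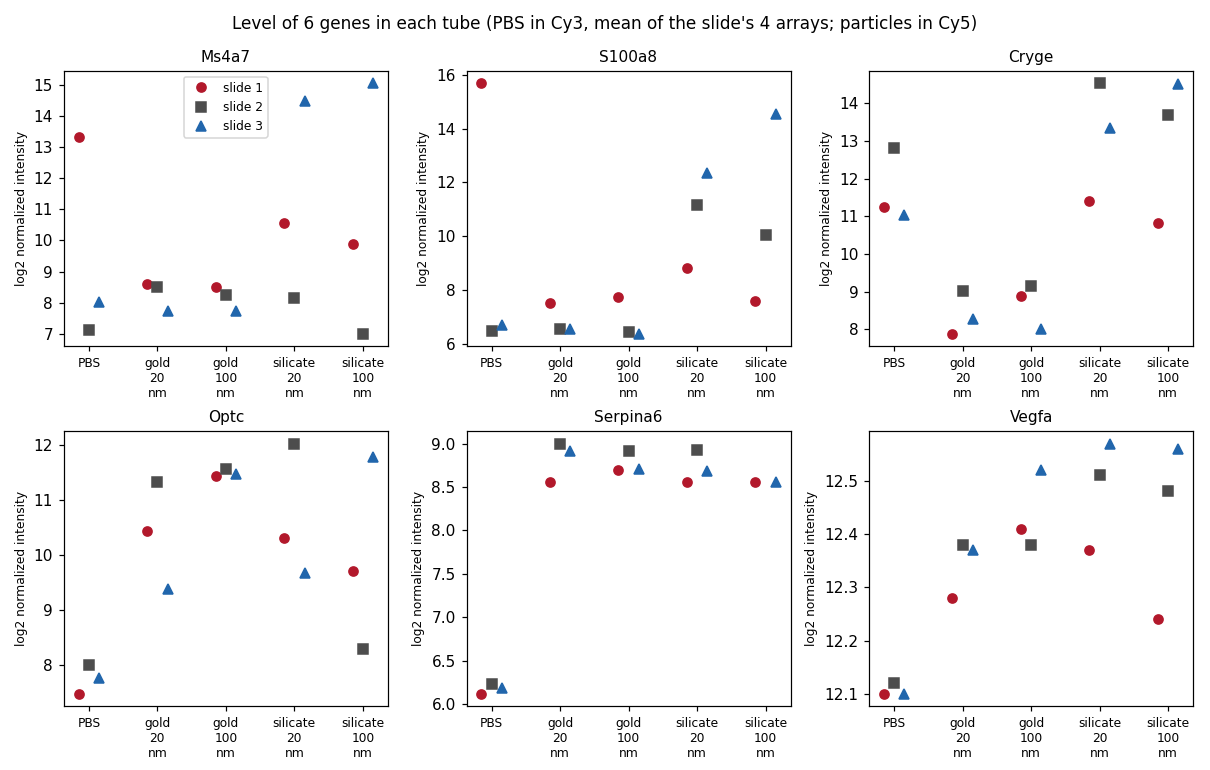
Normalized log2 intensity of 6 genes in each tube, with PBS tubes as the mean of the 4 Cy3 channels of their slide and particle tubes by group in Cy5. Serpina6 lies at 6.12 to 6.23 in the PBS tubes and at 8.56 to 9.00 in the particle tubes, and Cryge at 7.89 to 9.16 in the 6 gold tubes against 11.04 to 12.82 in the PBS tubes.

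Optc rose 7.32-fold over the 4 groups, on 12 of 12 arrays, with a log2 ratio of 2.87 ± 1.13 (SD, n = 12, adjusted p = 0.000295, and 0.0661 with the random block). Fbln1, Gpx3, Penk and Slc26a4 rose with log2 ratios of 2.50, 2.28, 2.25 and 2.09, each on 12 of 12 arrays, and with adjusted p of 0.0744 to 0.118 with the random block. The melanin synthesis genes Dct and Tyrp1 rose 4.87-fold and 4.65-fold, on 10 and 11 of 12 arrays (adjusted p of 0.0322 and 0.0134, and 0.3 and 0.252 with the random block). Their PBS levels spread from 10.07 to 13.88 and from 7.95 to 10.58. Among falls, Alas2, the heme synthesis enzyme gene of erythroid cells, Anp32a, Xlr4a, the growth factor gene Btc, Bub1b and the ciliary gene Arl6 had log2 ratios of -0.73, -0.70, -0.67, -0.55, -0.54 and -0.53, with adjusted p of 0.0566 to 0.251 with the random block. In total 1961 genes rose and 1474 fell. With the random block 339 rose and 54 fell, and all 393 were among the first count. The replicate block called 4122 higher and 3966 lower. Without slides 1, 2 and 3 in turn, 963, 267 and 2114 genes passed. The share of higher genes was 57.1%, and it was 30.2% with processed signals and 75.9% with median centring, so the balance of rises and falls has no settled direction.

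Pigment epithelium and melanocyte genes were higher over the 4 groups, with all 13 tested members above 0, 8 passing over all genes and 12 when adjusted over the list alone. Their median log2 ratio was 0.83 (adjusted p = 2.34e-05, and 0.992 with an estimated correlation), fry's adjusted p was 0.0389, and the slide medians were 1.93, 0.74 and 0.11. Mlana, Tyr and Rrh rose with log2 ratios of 1.98, 0.55 and 0.35. Muller glia genes had a median of 0.22, with Dkk3, Aqp4 and Clu higher by 0.48, 0.42 and 0.47 and 5 of 14 members higher over the list alone (adjusted p = 0.0412, 0.511 with an estimated correlation, and 0.00456 by fry). Their slide medians were 0.45, 0.05 and 0.24. Ganglion cell genes had a median of 0.17, with Slc17a6, Stmn2 and Gap43 higher by 0.49, 0.18 and 0.27, and amacrine and horizontal cell genes one of 0.23 with no member past the threshold (adjusted p = 0.0369 for both, and 0.992 for both with an estimated correlation). Slide medians were 0.56, 0.09 and -0.09 for ganglion cells and 0.62, 0.01 and -0.05 for amacrine and horizontal cells. Blood genes were lower, with a median of -0.64 over 7 genes and with Alas2 and Slc4a1 past the threshold (adjusted p = 0.0369, 0.511 with an estimated correlation, and 0.00456 by fry), and slide medians of -0.24, -0.30 and -0.31. These medians equal the values of Slc4a1 and hide unlike members. Hba-a1 and Alas2 had 0.28 and -0.09 on slide 1 and -1.70 and -1.45 on slide 3. S100a8, also a member, was at 15.69 in the PBS tube of slide 1 and at 6.48 and 6.71 in the others. Without slide 1, of these 5 lists pigment epithelium kept its call, with a median of 0.41 (adjusted p = 0.00802), and the others had adjusted p of 0.0576 to 0.791. Macrophage and microglia medians were -2.48, 0.46 and 1.33 on slides 1, 2 and 3. The single genes called in this paragraph missed the threshold with the random block.

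The other 25 lists did not pass over the 4 groups. For immune lists this covers slides that moved in opposite directions. Cytokine medians were -3.01, 0.37 and 1.54 on slides 1, 2 and 3. Interferon medians were -2.09, 0.36 and 0.94, and gliosis medians -1.69, 0.42 and 0.77. Without slide 1, camera with the preset correlation called 11 lists higher and 2 lower, against 4 and 1 with all arrays. No member passed for macrophages and microglia (median log2 ratio -0.17), inflammatory cytokines and adhesion (-0.49), interferon response (-0.24), reactive gliosis (-0.19), oxidative stress (-0.13), apoptosis and p53 (-0.24), endoplasmic reticulum stress (-0.08), immediate early genes (-0.04), cell cycle (-0.04), bipolar cells (0.09), lens (0.11), and cornea, ciliary body and muscle (0.47, adjusted p = 0.125). Median, mean and direction in camera differed in sign for lens, with a mean of 0.02 and a lower direction, for rods, with a mean of 0.06, for hypoxia and glycolysis, with a mean of -0.03, and for the cytosolic ribosome, with a mean of 0 and a higher direction. Each of a further 6 lists held 1 called gene, namely C2 (1.15) in complement (median 0.02), Per2 (0.14) in the circadian clock (0.05), Prph2 (0.56) in rods (-0.01), Pde6h (-0.21) in cones (-0.01), Slco1a4 (0.33) in endothelium and pericytes (-0.09) and Mtf1 (-0.17) in metal handling (-0.17). The dimmer probes of Mtf1 read 1.88 and -0.05, and its sign turned with the mean of all probes. Adjusted over the list alone, the counts were the same for clock, rods, cones and metal handling, and 0 for complement and for endothelium and pericytes.

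Angiogenesis genes moved both ways, with Vegfa and Angpt1 (0.53) higher, the receptors Flt1 (-0.42) and Flt4 (-0.11) lower and a median of 0.01 over 17 genes. Over that list alone 3 were higher and 2 lower. Hypoxia and glycolysis held 3 higher and 4 lower genes of 16 (median 0.04), with Eno1 at 0.35 and Ankrd37, Hif1a and Epas1 at -0.31, -0.23 and -0.16, the last of which was at 0 with median centring. Over the list alone 4 were higher and 5 lower. Barrier junction genes (median 0.05) had Cgn (0.37) and Cldn1 (0.30, and not well above background in PBS) higher, and 3 higher and 2 lower over the list alone. In heat shock (median -0.05) Hspa8 and Hspd1 (0.13) rose, and 3 genes, among them Hspa1a (-0.28) and Hsph1 (-0.10), fell, with the same counts over the list alone. Lysosome and autophagy (median -0.10) had Map1lc3b (0.15) higher and Atg7 (-0.16) lower. Oxidative phosphorylation (median -0.03) had 3 higher, among them Uqcrh and Atp5j (0.13), and 4 lower of 22, among them Cox5a (-0.21) and Cox4i1 (-0.18, and 0.04 with median centring), and 5 each way over the list alone. The cytosolic ribosome (median -0.02) had 3 higher, among them Rps14 and Rpl7 (0.24), and 1 lower, Rpl3 (-0.24), of 23, and 4 higher and 2 lower over the list alone. Further probes read 0.15, 0 and -0.05 for Rpl7, and 0.20 and -0.10 for Epas1. Of the genes of this paragraph, Vegfa, Hspa8, Uqcrh and Rps14 passed with the random block.

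The genes named in every case and reported here gave few calls. Over the 4 groups, the log2 ratio was -0.12 ± 1.51 for Gfap, the intermediate filament of activated glia (SD, n = 12, adjusted p = 0.866), -0.58 ± 1.87 for the stress enzyme gene Hmox1 (adjusted p = 0.541), -0.24 ± 1.78 for Mt2 (adjusted p = 0.796) and 0 ± 1.09 for Mt1 (adjusted p = 0.997), both metallothioneins. Kdr, the main Vegfa receptor, was at -0.08 ± 0.45 (adjusted p = 0.684). None of these 5 passed in any of the 4 groups. For Gfap, Hmox1 and Mt2 these means cover unlike slides. In the PBS tubes of slides 1, 2 and 3, Gfap was at 10.61, 8.93 and 9.16. Hmox1 was at 11.48, 7.57 and 8.30 there, and Mt2 at 16.94, 13.79 and 14.20. In the silicate 20 nm and 100 nm tubes of slide 3, Gfap was at 11.82 and 10.64. Hmox1 was at 9.68 and 9.15 in them, and Mt2 at 16.89 and 16.33. The missing calls therefore do not show that these genes stayed unchanged. The other Vegfa receptor, Flt1, fell with a log2 ratio of -0.42 ± 0.38 (adjusted p = 0.0208, and 0.268 with the random block).

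Calls overlapped between the 4 groups. Higher in all 4 were 108 genes, among them Serpina6, Prokr1, Dlgap5, Nxf3, Sntn, Tmigd1, Dsc3 and Rag1, and lower in all 4 were 8, among them Lrrc30. Of the 108, 42 were never well above background in PBS, and 6 had a further probe well above background on every array, with a median log2 ratio of -0.01 where the called probes of the same genes had 0.86. Further probes of another 4 were not above background to that extent. Their median SD over the 12 arrays was 0.2, against 0.19 for all genes. Between 2 groups, 119 to 181 genes were higher in both, where independent lists would share 1.24 to 3.17 and unchanged groups set against the same 3 PBS tubes shared 0 to 0.5 in 20 simulations. The simulated groups had a median of 3 calls, so they could share few, and their overlap does not gauge the part of the PBS tubes. In the real data, 9 to 20 genes were lower in both of 2 groups, and 0 were called in opposite directions. Log2 ratios of 2 groups correlated across genes at 0.29 to 0.85, with a median of 0.40, against 0.70 to 0.71 in the simulations. The covariance was 0.0201 to 0.0682 against 0.0645 to 0.0659, a difference of -0.0449 to 0.00227. Part of the overlap may come from the shared PBS tubes, and 3 tubes are too few to split.

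By size alone, 29 genes were at least 2-fold higher and 14 lower on all 3 arrays with gold 20 nm, 62 and 8 with gold 100 nm, 71 and 2 with silicate 20 nm, and 34 and 0 with silicate 100 nm. The lower genes are named after their values were seen. With gold 20 nm they included the crystallins Cryga, Crygb, Crygc, Crygd, Cryge, Crygf and Cryba4 and the lens genes Bfsp1 and Lgsn. With gold 100 nm they included Cryge, Crygf and Edn2, and with silicate 20 nm they were Csrp3 and Glb1l3. On all 12 arrays, 12 genes were at least 2-fold higher.

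Gold and silicate differed in 14 gene groups by camera, among them lens, immune and rod genes, and in 0 with an estimated correlation, and no single gene passed. Lens genes were lower with gold, with a median difference of -1.18 (adjusted p = 3.24e-08, and 0.777 with an estimated correlation) and of 0.05, -0.62 and -3.06 within slides 1, 2 and 3, and 4 members were lower when adjusted over the list alone. Corneal, ciliary body and muscle genes were also lower with gold, with a median of -0.90 (adjusted p = 0.00138, and 0.777 with an estimated correlation) and of -0.19, -0.35 and -1.64 within slides. Without both silicate arrays of slide 3, these 2 lists kept their calls, with medians of -0.93 and -0.56 (adjusted p of 8.92e-06 and 0.000919). The gold arrays of slide 3 stayed in, so gold on slides 1, 2 and 3 was set against silicate on slides 1 and 2. The medians within slides 1 and 2 were smaller in size, so the kept calls do not separate material from slide. Cryge had the largest difference among the genes with the smallest p, -4.52 ± 1.51 (SD, 3 slides, adjusted p = 0.175), followed in size by Dnaic2 at -0.63 ± 0.12 (0.15), Ell3 at 0.59 ± 0.06 (0.156) and Ect2 at 0.56 ± 0.16 (0.175), each in one direction on 3 of 3 slides. With the random block these 4 passed, at adjusted p of 0.0178, 0.0178, 0.0178 and 0.03. The SDs given for them are of differences within slides, while the adjusted p beside the SDs are from the fit without a slide term.

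Macrophage and microglia genes were lower with gold than with silicate by camera, with a median of -1.39 (adjusted p = 0.00241), as were cytokines and adhesion (-1.22, 0.0185), interferon response (-1.12, 0.00138), complement (-1.10, 0.0288) and reactive gliosis (-0.91, 0.000585). Of the 16 complement genes 4 stand in another list too, 3 of them in that of macrophages and microglia. Rod genes were higher with gold, with a median of 0.43 (adjusted p = 2.56e-08). With an estimated correlation the adjusted p was 0.777 for all 6. Within slides 1, 2 and 3 the medians were -0.76, 0.40 and -4.06 for macrophages and microglia, -0.24, 0.07 and -3.24 for cytokines, -0.61, 0.58 and -3.29 for interferon, -0.65, 0.53 and -3.28 for complement, -0.69, 0.47 and -2.56 for gliosis, and 0.20, -0.04 and 1.12 for rods. The differences were thus largest on slide 3. Without both silicate arrays of slide 3, none of the 6 passed, with medians of -0.02, 0.35, 0.05, -0.02, -0.11 and 0.06 and adjusted p of 0.898, 0.69, 0.779, 0.898, 0.779 and 0.272. The gold arrays of slide 3 stayed in here too, so this comparison was not balanced over slides. Immediate early genes (median -0.53), lysosome and autophagy (-0.43), angiogenesis (-0.25), endothelium and pericytes (-0.24), cytosolic ribosome (-0.10) and oxidative phosphorylation (0.07) passed as well with adjusted p of 0.000585 to 0.048, and likewise lost their calls with an estimated correlation (adjusted p = 0.777) and without those arrays. Of single genes, 0 passed in limma and 1204 had an unadjusted p under 0.05. The random block called 15 genes, 10 higher and 5 lower, and the replicate block 0 with 3778 at an unadjusted p under 0.05.

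Lens genes differed as a group by particle size, with a median difference of 1.37 between 100 nm and 20 nm (adjusted p = 1.72e-16, and 0.989 with an estimated correlation). Within slides it was 2.95, 0.90 and 0.22, and without slide 1 it was 0.58 (adjusted p = 0.00241). Reactive gliosis genes were lower with 100 nm, with a median of -0.45 (adjusted p = 0.037, and 0.989 with an estimated correlation), of -0.41, -0.36 and -0.41 within slides, and an adjusted p of 0.0566 without both silicate arrays of slide 3. Macrophage and microglia genes, which did not pass, had -0.46, -0.30 and -0.07 within slides. No single gene passed in limma, and 231 had an unadjusted p under 0.05. The replicate block and the random block called 0 as well, with 680 and 724 at an unadjusted p under 0.05. The smallest p belonged to Ect2 (0.26), Col6a2 (0.34), the oxytocin receptor gene Oxtr (-0.61) and Tbl1x (-0.30), with an adjusted p of 1.

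For gold, lens genes were higher with 100 nm than with 20 nm by a median of 1.55 (adjusted p = 1.65e-12, and 0.907 with an estimated correlation), with 3.09, 1.54 and -0.15 within slides. Pigment epithelium genes were higher by 0.62 (adjusted p = 0.000229, and 0.987 with an estimated correlation), with 1.38, 0.30 and 0.29 within slides, and barrier junction genes by 0.13 (adjusted p = 0.038, 0.561 with an estimated correlation, and 0.0654 with the replicate block). Gliosis genes were lower, with a median of -0.56 (adjusted p = 0.00467, and 0.987 with an estimated correlation) and with -0.55, -0.84 and -0.43 within slides. Macrophage and microglia genes had -0.32, -0.64 and -0.28 and interferon genes -0.48, -0.55 and -0.23 within slides, and neither list passed (adjusted p of 0.427 and 0.136). For silicate, lens genes were higher with 100 nm by a median of 1.19 (adjusted p = 6.01e-07, and 0.996 with an estimated correlation), with 2.70, 0.17 and 0.56 within slides and an adjusted p of 0.107 without slide 1. No single gene passed in limma in either material, where 184 and 218 had an unadjusted p under 0.05. With the replicate block 564 and 637 had one and with the random block 617 and 673, and both called 0. The smallest p belonged to Evc (0.43), Snrnp70 (0.43), Car1 (-0.21) and Dusp8 (-0.28) for gold and to Col6a2 (0.53), Mdh1b (0.36), Oxtr (-0.82) and Sytl1 (-0.73) for silicate, with an adjusted p of 1.

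The size effect differed between the materials for pigment epithelium genes, with a median difference of 1.23 for gold over silicate (adjusted p = 3.63e-05, and 0.998 with an estimated correlation), and 0.36 without slide 1 (adjusted p = 0.00101). It also differed for corneal, ciliary body and muscle genes (0.78, adjusted p = 0.0285, and 0.998 with an estimated correlation), Muller glia (0.29, 0.0328 and 0.256) and barrier junction genes (0.17, 0.0285 and 0.256). Within slides the medians were 1.67, 1.09 and 0.29 for pigment epithelium, 1.71, 1.59 and -0.86 for the corneal list, 0.11, 0.36 and 0.26 for Muller glia and 0.27, 0.06 and 0.04 for barrier junctions. Without slide 1 the corneal and barrier lists had adjusted p of 0.348 and 0.278. Of single genes, 0 passed in limma, in the replicate block and in the random block, where 141, 504 and 538 had an unadjusted p under 0.05. The smallest p belonged to Sytl1 (0.98), the deiodinase gene Dio3 (0.87), Car1 (-0.34) and Asf1b (-0.72), with an adjusted p of 1.

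At 20 nm, gold was lower than silicate for lens genes, with a median of -1.52 (adjusted p = 1.23e-07, and 0.657 with an estimated correlation), 3 lower members over the list alone and -0.41, -1.36 and -2.62 within slides. Corneal, ciliary body and muscle genes (median -1.39, adjusted p = 0.000123, and 0.559 with an estimated correlation) had -1.84, -0.92 and -0.92 within slides, and immediate early genes a median of -0.56 (0.0171 and 0.657), with -0.13, -0.46 and -1.08 within slides. Rod genes were higher with gold (0.47, 9.63e-07 and 0.845), with 0.29, 0.01 and 1.16 within slides, and so were oxidative phosphorylation genes (0.09, 0.000123 and 0.559), with 0.03, 0.06 and 0.24. Macrophage and microglia genes, which did not pass (adjusted p = 0.0612), had -0.69, 0.64 and -3.77 on the same slides. Gucy2d (0.91), Hdc (1.25), the trefoil factor gene Tff1 (-1.52) and Dnaic2 (-0.62) had the smallest p, with an adjusted p of 0.831 for Dnaic2, and no gene passed in limma, where 760 had an unadjusted p under 0.05. The replicate and the random block called 0, with 2226 and 2070 at an unadjusted p under 0.05.

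At 100 nm, gold was lower than silicate for macrophage and microglia genes (median -1.59, adjusted p = 0.00351), complement (-1.34, 0.0133), cytokines (-1.34, 0.00545), interferon response (-1.29, 0.00045), gliosis (-1.20, 5.03e-05), lens (-0.80, 8.12e-06), immediate early genes (-0.47, 0.004), endothelium (-0.30, 0.0133), angiogenesis (-0.27, 0.032, and 0.0704 with the replicate block) and ribosome (-0.11, 0.00761). It was higher for pigment epithelium genes (0.67, 0.00352) and rods (0.40, 4.13e-06). With an estimated correlation the adjusted p was 0.699 for each of these lists. Slide 3 had the largest differences in most of them. Within slides 1, 2 and 3, the medians were -0.48, 0.09 and -4.23 for macrophages and microglia, -0.72, 0.23 and -3.63 for complement, -0.16, -0.11 and -3.73 for cytokines, -0.75, 0.25 and -3.31 for interferon response and -0.70, -0.06 and -2.75 for gliosis. They were 0.25, 0.26 and -3.51 for lens, -0.40, -0.39 and -0.47 for immediate early genes, -0.03, 0.05 and -0.70 for endothelium, 0.08, 0.13 and -0.88 for angiogenesis and 0.04, -0.04 and -0.34 for the ribosome. Rods had 0.13, -0.05 and 1.13, and pigment epithelium 0.89, 1.24 and -0.05, the latter smallest on slide 3. Cryge (-4.30), Dnaic2 (-0.65), Ell3 (0.61) and Ect2 (0.61) had the smallest p, with an adjusted p of 1, and no gene passed in limma, where 413 had an unadjusted p under 0.05. The replicate and the random block called 0, with 1443 and 1352 at an unadjusted p under 0.05.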

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

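The tests of the channels, of the whole slide, of red blood cells in the PBS tube and of a dye effect, the test of lens genes against gamma-crystallins, and the assignment of channels by whole slide were chosen only after the results were seen. The correlation of lens genes and the other counts over groupings of the arrays were planned.

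Between gold and silicate, 14 gene lists differed by camera's test of the difference. The median differences were -1.39 for macrophages and microglia, -1.22 for cytokines and adhesion, -1.12 for interferon response, -1.10 for complement, -0.91 for reactive gliosis, 0.43 for rods, -1.18 for lens, -0.90 for cornea, ciliary body and muscle, -0.53 for immediate early genes, -0.43 for lysosome and autophagy, -0.25 for angiogenesis, -0.24 for endothelium and pericytes, -0.10 for the cytosolic ribosome and 0.07 for oxidative phosphorylation. Between 100 nm and 20 nm, lens genes differed by 1.37 and reactive gliosis genes by -0.45. The size effect of gold minus that of silicate was 1.23 for pigment epithelium and melanocytes, 0.78 for cornea, ciliary body and muscle, 0.29 for Muller glia and 0.17 for barrier junctions. None of these calls held with an estimated correlation. Lens genes had medians below 0 on every gold 20 nm array and above 0 on every silicate 100 nm array, 3 arrays each, and the middle value of gold 20 nm minus that of silicate 100 nm was -3.37, a difference that was not tested on its own.

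In the PBS tube of slide 1, 80 genes of 5 inflammatory lists stood a median of 2.93 log2 above the PBS tubes of the other slides, and the silicate tubes of slide 3 carried the same lists at 1.96 to 3.54. Exchanged channels on slide 1 are excluded, because Cy3 there varied less within the slide than Cy5, with a ratio of SDs of 0.47, as on the other slides. A defect of the whole slide is excluded as the whole cause, since the gold tubes of slide 1 stood a median of 0.25 (quartiles -0.02 and 0.56) above the gold tubes of slides 2 and 3 in the same genes, but 26 of the 80 stood more than 0.5 above, Lcn2 and Timp1 by 4.94 and 4.42 where the PBS tube had 6.50 and 6.78, so a part stays open for such genes. The 6.50 of Lcn2 rests in part on its Cy3 readings on slide 3, which had an SD of 2.44 over the 4 arrays. Red blood cells in the PBS tube of slide 1 are excluded, with a median log2 ratio of 0 over 4 erythroid genes. An inflamed or injured eye in single pools, a wrong tube and white blood cells remain open and untested, as does particle exposure for the silicate tubes of slide 3, and no biological explanation of that PBS tube was tested, since the design names none.

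Genes called higher in all 4 groups, 108 in number, had a median log2 ratio of 1.01 and a median SD of 0.2 over the 12 arrays. A dye effect of single probes is a candidate explanation, because other probes well above background on every array had a median of -0.01 (range -0.18 to 0.65) where the called probes had 0.86, over 6 genes with such a probe, all with called probes at 16.71 to 17.86. The set was narrowed to these genes after the same comparison over all genes above 1 log2 was undecided. The remaining 54 genes above 1 log2, Optc and Fbln1 among the named ones, had a median SD of 0.84, and 14 of them with a further probe had medians of 1.18 and 0.55. Particle exposure remains open for the genes without such a probe, 4 with one near background among them, since no array had the dyes exchanged. The median does not settle each of the 6 genes either. Other probes read 0.65 for Fam177a2 and 0.29 for Kctd14, where the called probes had 1.03 and 1.20. Those of Luc7l2, Sp110, Synrg and Ubtf read -0.09, -0.18, -0.03 and 0.

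Cryge and Crygf were low in gold tubes. Cryge was at 7.89 to 9.16 in the 6 gold tubes, 10.82 to 14.53 in the 6 silicate tubes and 11.04 to 12.82 in the 3 PBS tubes, and Crygf, chosen after its values were seen, at 7.06 to 8.11, 9.59 to 13.63 and 9.78 to 11.89. Gold minus silicate was taken for Cryga, Crygb, Crygc and Crygd, without Cryge and Crygf. That for Mip, Lim2, Bfsp1, Bfsp2 and Lgsn was subtracted from it. The result was -1.05, -2.97 and -1.21 on the 3 slides, with a mean of -1.74 and an SD of 1.06. A single amount of lens tissue for all lens genes would give values near 0. It is not excluded as the whole cause, because the same data had already shown these crystallins at least 2-fold lower with gold 20 nm. The 3 slides are also few. A part for lens tissue in the tubes stays open, since Pearson's r between both gene sets was 0.43 over 12 arrays (permutation p = 0.17, Spearman's rho 0.53 with p = 0.08, r 0.29 without the 2 farthest arrays), and 0.58 over Cy5 levels (permutation p = 0.049, rho 0.52 with p = 0.083, r 0.47 without the 2 farthest tubes), adjusted p of 0.17 and 0.11 for r and 0.11 for both rho. All 17 listed lens genes passed the filter in retina, 0 of them stand in another list, and an effect of gold on crystallin transcripts may remain, untested.

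Other groupings of the arrays bear on chance. For gold against silicate, 22 of 100 groupings of the 12 arrays gave at least the real 1204 genes at an unadjusted p under 0.05, with up to 9752 in another grouping, so chance cannot be excluded. With groups reassigned within slides and the slide as a block, 2 of 100 gave at least the real 3778, with up to 3888 in the other. That share lies under 0.05, the limit set beforehand, so this count argues against chance within slides. The other grouping exceeded the real one, however, and the same fit called 0 single genes. Place on the slide also equals group, so the count cannot tell material from place. For 100 nm against 20 nm, 82 of 100 reached the real 231, with up to 4812, and within slides 47 of 100 reached 680, with up to 4020. For the difference of the size effects, 86 of 100 reached 141, with up to 10519, and within slides 57 of 100 reached 504, with up to 3641. Groupings that call several times the real count point to a structure of the samples.

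For single pairs of groups, the 10 splits of 6 arrays are too few for a share under 0.05. As many genes were reached by 9 of 10 splits for gold 100 nm against gold 20 nm (real 184, highest other 958), 8 for silicate 100 nm against silicate 20 nm (218 and 7862), 5 for gold 20 nm against silicate 20 nm (760 and 2034) and 6 for gold 100 nm against silicate 100 nm (413 and 2602). For the 4 groups together against PBS, the 4 assignments of the channels by whole slide are too few too, where 1, the real one, reached 3435 calls and the highest other called 124. Assignments array by array (1 of 100 reached 3435, highest other 2) treat arrays that share a PBS tube as independent and decide nothing. For single groups against PBS, 4 assignments are too few, with the real one alone reaching 164, 228, 485 and 230 calls for gold 20 nm, gold 100 nm, silicate 20 nm and silicate 100 nm, and 3, 2, 2 and 1 in the highest other.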

How the results depend on the processing

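Leaving out a slide or the silicate arrays of slide 3 and the separate channels were chosen after seeing the data. For genes past the threshold, the counts without a block were 164, 228, 485 and 230 for gold 20 nm, gold 100 nm, silicate 20 nm and silicate 100 nm, and 3435 for all particles, in this order below. The replicate block, paired by slide, called 1038, 1564, 2037, 938 and 8088, and the random block 289 for silicate 20 nm, 393 for all particles and 15 for gold against silicate. Median centring called 350, 421 and 479 for gold 20 nm, gold 100 nm and silicate 100 nm. The stricter filter (both channels above background on all 12 arrays) left 11, 63, 237 and 34, an intensity trend with robust spread 62, 47, 60 and 50, and the deposited values 321 for silicate 20 nm. Only the groups of the comparison left 0 in each of the 4 groups, with fewer arrays for the spread, and was not applicable to the 4 contrasts over all groups. Without slide 1 the counts were 54, 34, 49, 41 and 963, without slide 2 they were 12, 4, 8, 7 and 267, and without slide 3 they were 8, 28, 176, 37 and 2114, with fewer arrays. Without both silicate arrays of slide 3 they were 222 and 129 for silicate 20 nm and 100 nm, and 1 each for gold against silicate and for gold 20 nm against silicate 20 nm. Separate channels gave 125, 127 and 128 for gold 100 nm, silicate 20 nm and silicate 100 nm, 190 for all particles and 5 for gold against silicate. Other counts stayed within 1.5 times. Aquantile leaves ratios within an array as they are and moved nothing. Except for the designs with fewer arrays, the cause was not tested.

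With single arrays left out, counts ranged from 59 to 189 for gold 20 nm, 54 to 224 for gold 100 nm, 70 to 487 for silicate 20 nm, 63 to 213 for silicate 100 nm and 2283 to 3340 for all particles, with one group then at 2 arrays. Each replicate of gold 20 nm moved its own count by over 1.5 times, as did each of gold 100 nm, the lowest being without replicate 2 in both. Silicate 20 nm moved without each of its own replicates (lowest without replicate 2), without gold 20 nm replicates 2 and 3, gold 100 nm replicates 1 and 2, and silicate 100 nm replicate 1. Silicate 100 nm moved without each of its own (lowest without replicate 1), without gold 20 nm replicates 2 and 3 and gold 100 nm replicate 2. All particles moved without gold 20 nm replicate 1. Gold against silicate and gold 20 nm against silicate 20 nm had 0 to 1, the 1 without silicate 20 nm replicate 3, and the other 5 contrasts between particles had 0.

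Camera called 62 lists over the 12 contrasts, 111 with the replicate block, 126 without slide 1 and 0 with an estimated correlation. For silicate 20 nm, 14 lists were higher and 3 lower without slide 1, against 3 and 0 with all arrays. For silicate 100 nm they were 15 and 2, against 2 and 0. Genes at 2-fold or more on all 3 arrays were 43, 70, 73 and 34, against 169, 196, 187 and 147 with processed signals, and 63 for silicate 100 nm with median centring. The median correlation between groups of 0.40 was 0.81 without both silicate arrays of slide 3. Mtf1 turned from lower to higher with the mean of all probes, to 0.63, 0.53, 0.52 and 0.53 in the 4 groups and 0.55 over all particles, where a dim probe read 1.88. With median centring Epas1 was at 0 and Cox4i1 at 0.04 over all particles. Of 27338 values of named genes under alternatives, 25484 kept direction and side of the threshold, 1115 lost a call, 245 gained one, 7 reversed and 487 changed sign without a call. The 62 lists that passed had 434 values under alternatives, of which 310 kept the call and 124 lost it. The replicate block gave a call to 121 of 990 values of named genes, took none, and changed no call between particle groups for single genes. Signal over background limits genes such as Serpina6, whose PBS level was not well above it on any array.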

Other observations

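Levels of single tubes are given here for genes chosen after their values were seen, without a test. Lcn2, an acute phase protein of reactive glia, was at 17.49 in the PBS tube of slide 1 and at 9.98 and 11.99 in the other PBS tubes. The SD over the 4 arrays of a slide was 0.04, 0.08 and 2.44 on slides 1, 2 and 3. The 11.99 of slide 3 is thus a mean of unlike readings and not a stable level of 1 tube. In the 4 particle tubes of slide 1, Lcn2 was at 15.13 to 15.53, above the 10.11 to 11.21 of the particle tubes of slide 2. S100a8 was at 7.51 to 8.80 in the particle tubes of slide 1. That was above the 6.54 and 6.44 of the gold tubes of slide 2 and below the 11.16 and 10.06 of its silicate tubes. Levels of different probes cannot be set against each other. S100a9 was at 13.22 and 11.75 in the silicate tubes of slide 2, and at 7.44 and 7.22 in the gold tubes of that slide. The cytokine gene Il1b was at 14.01 in the PBS tube of slide 1, at 8.27 to 8.60 in the particle tubes of that slide, and at 11.01 and 13.21 in the silicate 20 nm and 100 nm tubes of slide 3. On slide 2 it was at 8.51 and 8.14 in the silicate tubes, 6.56 and 6.32 in the gold tubes and 6.20 in PBS. Cd74, of antigen presentation, reached 15.18 and 13.89 in the silicate 20 nm and 100 nm tubes of slide 3, above the 12.51 of the PBS tube of slide 1.

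Markers of tissue next to the retina differed between PBS tubes too. The corneal keratin gene Krt12 was at 13.16 in the PBS tube of slide 3, at 7.16 and 7.27 in the other PBS tubes, and at 7.24 to 9.15 in the particle tubes. The hemoglobin gene Hba-a1 was at 12.63, 13.28 and 14.26 in PBS on slides 1, 2 and 3, while the mean of the particle tubes was at 12.91, 12.78 and 12.55, with log2 ratios of 0.28, -0.50 and -1.70. Dct was at 10.07, 11.78 and 13.88 in PBS and at 12.38 to 15.80 in the particle tubes.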
